A study of Mus musculus with 20 samples.

How the data were processed

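Strand-specific libraries of polyadenylated RNA (TruSeq Stranded mRNA, per the labels' protocols) were sequenced from WT and TKO cells of the mouse embryonic stem cell line ES-E14TG2a as stem cells and on 4 later days of neural differentiation (D0 to D8), with 2 biological replicates per genotype and day according to the labels, 20 libraries in all. Each deposited table holds 119414 Ensembl transcripts of 1 library. The estimated counts are reads or fragments assigned to each transcript by kallisto and not scaled to depth, per the submitters' processing notes, which name GRCm38, Trim Galore 0.6.2 and kallisto without its version, the role of Trim Galore or the transcript set. The deposited TPM values are the estimated counts divided by effective length and scaled to a fixed sum, per the file headers. Lengths and effective lengths are in bases per the file headers. The labels do not define TKO.

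Transcripts were matched to genes of the GENCODE M21 annotation by identifier, 116161 with the same version and 116728 in all, and the 2686 without a match, which held 0.94% to 1.1% of the counts of a library, stayed out of the tests. Estimated counts were summed per gene and rounded to whole numbers, for 35975 genes, of which 21897 are protein-coding and 13518 pseudogenes. Totals per library ran from 26015282 in TKO D2 replicate 2 to 38074768 in WT D2 replicate 2. Levels are CPM, counts scaled to a library of 1e+06 after TMM scaling, and their precision is limited by the 2 libraries per group. Counting intervals at 95% and floors of 3 counts cover counting error only. The share of the 31-mers of each gene that also occur in transcripts of other genes was computed from the annotated sequences, and genes with at least 10% are named as uncertain, since kallisto divides such reads between them.

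The choices of test, comparisons, gene lists, named genes and alternatives were made before the data were examined, apart from those named as added. All 20 libraries were fitted together with edgeR 4.0.16 (quasi-likelihood F test, TMM, filterByExpr on the 10 groups), in which 18555 genes were tested with a common biological coefficient of variation of 0.069 and 10 residual degrees of freedom. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were TKO against WT at each of the 5 days, each later day against D0 within a genotype, the interaction of genotype with D8 against D0, and a joint test of the interaction at all 4 later days.

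Lists of genes were written from general knowledge for DNA methylation machinery, naive, core, and formative and primed pluripotency, neural progenitors, anterior neural, posterior Hox and Cdx, neurons, glia, neural crest, primitive streak and mesoderm, endoderm, surface ectoderm and epithelia, trophoblast, mesenchyme and fibroblasts, methylation-dependent germline, germ cell specification, the Rhox cluster, imprinted genes, Xlr and X-inactivation, 2-cell-like cells, interferon response, p53 targets, stress and unfolded protein response, proliferation, the Wnt, Notch, Shh, retinoic acid, Bmp and Tgfb, and Fgf and Mapk pathways, glycolysis and hypoxia, mitochondrially encoded genes and Y-linked genes. These 34 lists were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the lists within a comparison. Members of one list can also belong to another, as for 9 of the 18 formative and primed genes.

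Genes named by rule were Dnmt1, Dnmt3a, Dnmt3b and Tet1, Tet2 and Tet3 in every group, as possible targets of a triple knockout, and the markers Pou5f1, Nanog, Zfp42, Fgf5, Sox1, Pax6, Nes, Tubb3, Dazl, T and Sox17. For TKO against WT at each day, D8 against D0 and the interaction, the rule added the 6 highest and 6 lowest genes among those that passed with at least 5 CPM in a group and, outside the interaction, with both libraries of one group above both of the other, without predicted or clone names. Per list it added up to 4 members with the largest change among those that passed. Where fewer are printed, they were taken from the top, or the members ahead of them are named, except that some genes are not reported here.

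The alternatives fixed in advance were relative log expression scaling, no low-count filter, the replicate number as a block, counts from length-scaled TPM, an adjusted p under 0.01, a change of at least 2-fold, DESeq2 1.42.0, a fit of the compared groups alone, leaving out each library in turn, and camera with an estimated correlation or fry in place of camera. When a group is left with 1 library, that library is assumed to vary like the other groups. Added after the data were seen were protein-coding genes alone, genes with under 10% shared 31-mers, a fit without the D8 libraries, comparisons of D8 with D6 and families of genes with a common name stem. Tested on simulated data of 17949 genes with 200 seeded changes between TKO and WT at D0, the fit recovered 63 of 67 at 1.5-fold, all 67 at 2-fold and all 66 at 4-fold, with 12 other genes called. Simulated counts took the same fitted spread per gene in every group, and seeded genes had at least 5 CPM in WT D0. The simulation therefore cannot show how the test behaves with the wider spread between the real WT D0 libraries. Work was done in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.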

Results

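Polyadenylated RNA was sequenced from WT and TKO cells of the mouse line ES-E14TG2a, taken as stem cells in serum and LIF at D0 and at D2, D4, D6 and D8 of neural progenitor differentiation on laminin in N2B27 medium. The 10 groups held 2 biological replicate libraries each, 20 in all. Between 20069 and 22129 genes had a count in a library, and the 10 genes with most counts took 3.52% to 8.04% of a library. Levels are in CPM (counts per 1e+06) as the mean ± SD of the 2 libraries of a group (n = 2). A fold against a group with 0 counts is a lower bound against a floor of 3 counts over the group, and where a group held 1 to 3 counts the ratio of counts is given with its 95% counting interval. Genes are called higher or lower only where the edgeR quasi-likelihood test passed (adjusted p < 0.05), list counts are of members tested, and a median is that of their log2 fold changes. For each named gene with a printed fold change between 2 groups, both libraries of one group lay above both of the other.

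Principal components of the 500 most variable genes placed the libraries by day and by genotype. The first component held 65.6% of the variance and followed the days in WT, and the second parted the genotypes. The TKO D8 libraries lay at 20.6 and 21.3 on the first component, short of the TKO D6 libraries at 44.22 and 48.82 and of the WT D8 libraries at 71.2 and 73.88. Pou5f1, the pluripotency factor Oct4, gave the same picture in a single gene. In WT it went from 1312 ± 39.4 CPM at D0 to 4.4 ± 1.92 at D6 and 12.5 ± 7.13 at D8, and in TKO from 1309.7 ± 22.9 to 49.8 ± 7.89 and then 526 ± 37.5. The libraries of WT D0 stood further apart than those of any other group, with a chi-square per degree of freedom of 29.52 between replicates. Bnip3 at 157 ± 125 CPM and Trib3 at 54.4 ± 54.6 CPM differed between them, both named after their values were seen, with 30.1% of Bnip3 shared, and no test was made between these libraries.

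**Figure D1:**
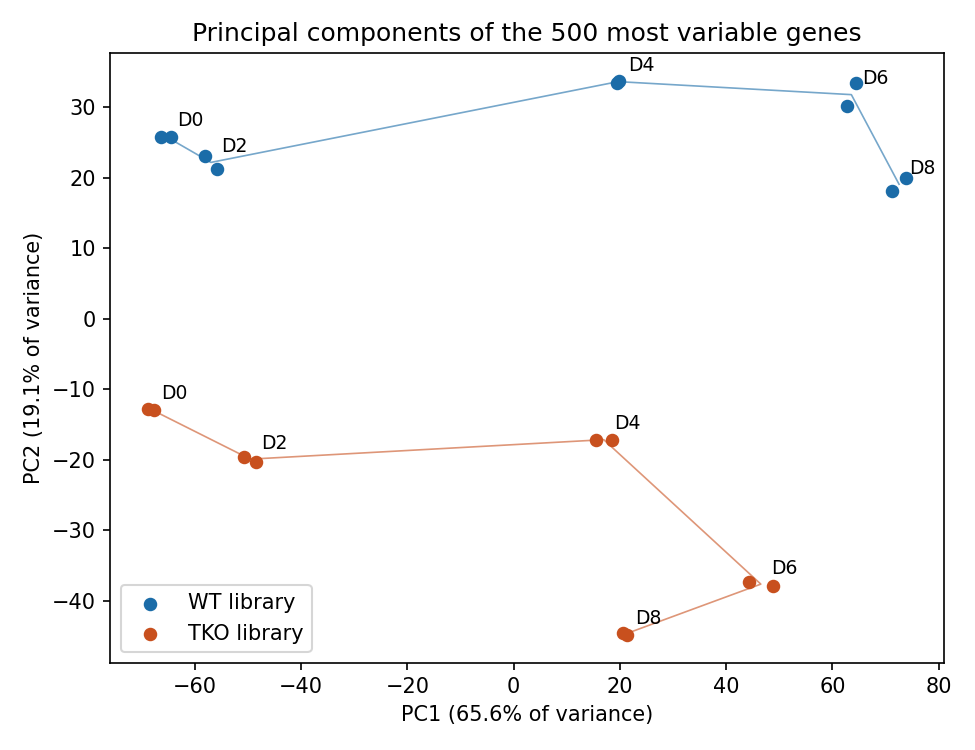
The first and second principal component of each of the 20 libraries, from log2 CPM of the 500 most variable genes, with points for libraries and lines joining group means by day. The TKO D8 libraries lie at 20.6 and 21.3 on the first component and the WT D8 libraries at 71.2 and 73.88.

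The labels do not spell out which genes TKO stands for, so the DNA methyltransferase and Tet genes were read in every group first. Transcripts of Dnmt1, the maintenance methyltransferase, were lower in TKO at all 5 days. The WT levels from D0 to D8 were 441 ± 57.7, 481 ± 4.08, 433 ± 22.3, 390.0 ± 22.8 and 295 ± 3.09 CPM, and the TKO levels were 78.7 ± 5.47, 79.7 ± 1.65, 91.1 ± 7.84, 82.7 ± 7.35 and 81.4 ± 0.118 CPM. The largest fall of Dnmt1 was at D2 (log2 fold change -2.59, SE 0.09, adjusted p = 8.16e-13). Dnmt3a, a de novo methyltransferase, was 98.9 ± 7.66, 609 ± 3.14, 89.0 ± 4.75, 106 ± 2.8 and 103 ± 0.336 CPM in WT and 23.3 ± 1.58, 64.3 ± 2.11, 8.38 ± 0.722, 9.27 ± 0.0853 and 30.5 ± 2.45 CPM in TKO. It was lowest against WT at D6 (log2 fold change -3.51, SE 0.083, adjusted p = 1e-15). Dnmt3b, the other de novo enzyme, peaked in WT at D2 with 1386 ± 86.8 CPM against 111 ± 1.64 in TKO (log2 fold change -3.64, SE 0.13, adjusted p = 9.39e-13). It was higher in TKO at D8, at 88.2 ± 8.28 against 46.6 ± 11.8 CPM (log2 fold change 0.92, SE 0.12, adjusted p = 3.07e-06). Dnmt3b shares 15.2% of its 31-mers with other genes, and polyadenylated transcripts that remain from an edited gene are counted here whether or not they encode a protein. Tet1, a methylcytosine dioxygenase, stood at 732 ± 1.36 CPM in WT and 787 ± 56.8 in TKO at D0 and was higher in TKO at D8 (55.5 ± 0.591 and 184 ± 4.56 CPM, log2 fold change 1.73, SE 0.082, adjusted p = 5.38e-12). Tet2 at D8 was lower in TKO (87.0 ± 2.35 and 30.9 ± 1.78 CPM, log2 fold change -1.49, SE 0.1), as was Tet3 (219 ± 1.45 and 86.8 ± 0.747 CPM, log2 fold change -1.33, SE 0.14). On GRCm38, Dnmt1 (ENSMUSG00000004099.16) lies on chromosome 9 from 20907209 to 20959888, Dnmt3a (ENSMUSG00000020661.15) lies on chromosome 12 from 3806007 to 3914443 and Dnmt3b (ENSMUSG00000027478.15) lies on chromosome 2 from 153649450 to 153687730.

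**Figure D2:**
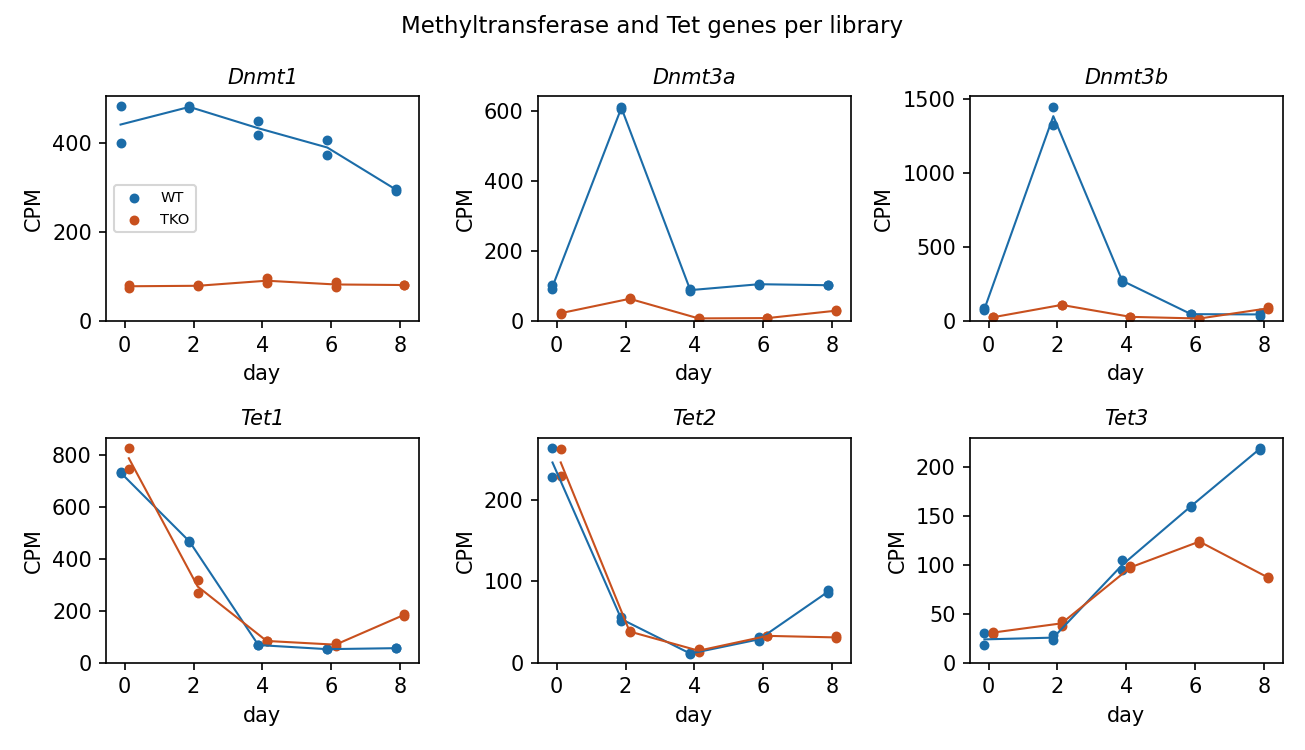
CPM of Dnmt1, Dnmt3a, Dnmt3b, Tet1, Tet2 and Tet3 per library by day, with lines through the means of 2 libraries. Both TKO libraries lie below both WT libraries for Dnmt1 and Dnmt3a at all 5 days.

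What changed in WT cells over the differentiation was read from D8 against D0. Genes of the stem cell state fell and neural genes rose. Among naive pluripotency genes, Tcl1 went from 146 ± 6.66 to 0.19 ± 0.0963 CPM (log2 fold change -9.56, SE 0.2, adjusted p = 4.62e-17) and Fgf4 from 221 ± 32.7 to 0.6 ± 0.164 CPM (log2 fold change -8.52, SE 0.2). The 18 naive pluripotency genes included 0 higher and 18 lower (median -6.48, camera adjusted p = 2.27e-19). Of 15 core pluripotency genes, 0 were higher and 15 lower (median -5.56, camera adjusted p = 2.08e-12). Among the latter, Tdgf1, a Nodal co-receptor, went from 920.3 ± 245 to 1.95 ± 0.816 CPM, with 17.4% of its 31-mers shared with other genes. Of 30 neural progenitor genes, 30 were higher and 0 lower (median 5.72, camera adjusted p = 5.9e-37). Dbx1, a homeobox gene of the neural tube, was at 0.02 ± 0.0226 CPM at D0 and 193 ± 3.49 at D8 (count ratio 12100, 95% counting interval 2180 to 479000). Neuron genes gave 30 higher and 0 lower of 30 (median 5.73, camera adjusted p = 1.74e-30). Dcx, a microtubule protein of young neurons, went from 0.08 ± 0.0217 to 718 ± 7.88 CPM (log2 fold change 13.05, SE 0.28), and Neurod4 from 0 to 25.5 ± 3.45 CPM (at least 529-fold higher). The 12 Notch pathway genes included 10 higher, 1 lower and 1 not passing (median 3.50, camera adjusted p = 1.21e-06). Hes5, a Notch effector, reached 79.1 ± 0.641 CPM (log2 fold change 7.72, SE 0.21). Among the highest genes of the comparison were Tenm2 (at least 2110-fold higher), Otp, a homeobox gene of hypothalamic neurons, Dbx1, Clvs1 and Chl1.

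Groups outside the neural lineage moved in WT too. Methylation-dependent germline genes gave 4 higher, 31 lower and 4 not passing of 39 (median -4.14, -3.48 with members at 0 set to their bound, camera adjusted p = 4.56e-07, and adjusted p = 0.151 with an estimated correlation). Stra8, a meiosis gene induced by retinoic acid, went from 5.84 ± 0.812 CPM to 0 (at least 133-fold lower). Of 18 germ cell specification genes, 1 was higher, 14 lower and 3 did not pass (median -3.92, camera adjusted p = 9.24e-09, and adjusted p = 0.0533 with an estimated correlation). The 20 proliferation genes included 1 higher, 17 lower and 2 not passing (median -1.10, camera adjusted p = 2.18e-05, and adjusted p = 0.269 with an estimated correlation). Of 20 glycolysis and hypoxia genes, 0 were higher, 19 lower and 1 did not pass (median -2.37, camera adjusted p = 2.03e-05, and adjusted p = 0.309 with an estimated correlation). Pdk1, a brake on pyruvate oxidation, went from 353 ± 94.1 to 7.75 ± 0.583 CPM (log2 fold change -5.51, SE 0.15), with the 2 WT D0 libraries far apart in several of these genes. Imprinted genes gave 24 higher, 6 lower and 2 not passing of 32 (median 1.58, camera adjusted p = 2.18e-05). Peg12 rose from 0.8 ± 0.0351 to 108 ± 3.14 CPM (log2 fold change 7.06, SE 0.12). The 16 mesenchyme and fibroblast genes included 14 higher and 2 lower (median 2.06, camera adjusted p = 0.0234, and adjusted p = 0.275 with an estimated correlation). For these lists, adjusted over the list alone, the counts were the same except for methylation-dependent germline (4 higher and 32 lower). By edgeR, 14247 of 18555 genes tested passed at D8 against D0, 7017 higher and 7230 lower, after 10154 at D2, 12030 at D4 and 13191 at D6.

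The same days were compared in TKO cells. They too raised neural genes and lowered naive genes, while core pluripotency genes fell far less than in WT. Of 30 neural progenitor genes, 29 were higher, 0 lower and 1 did not pass (median 3.71, camera adjusted p = 4.89e-37). Fabp7, a radial glia lipid-binding protein, went from 0 to 113 ± 2.64 CPM (at least 2110-fold higher), and Dbx1 from 0 to 23.2 ± 3.16 CPM (at least 434-fold higher). Neuron genes gave 27 higher, 1 lower and 2 not passing of 30 (median 3.31, camera adjusted p = 3.63e-24). Nhlh2, a neuronal helix-loop-helix factor, went from 0 to 54.8 ± 4.26 CPM (at least 1020-fold higher). The 12 Notch pathway genes included 10 higher, 1 lower and 1 not passing (median 2.97, camera adjusted p = 1.31e-08). Naive pluripotency genes gave 0 higher and 18 lower of 18 (median -3.24, camera adjusted p = 5.33e-24). Tcl1 went from 132 ± 0.584 to 2.49 ± 0.14 CPM (log2 fold change -5.73, SE 0.14, adjusted p = 1.54e-15) and Tbx3 from 77.8 ± 0.0598 to 3.61 ± 0.563 CPM (log2 fold change -4.42, SE 0.19). Of 15 core pluripotency genes, 2 were higher, 12 lower and 1 did not pass (median -1.23, camera adjusted p = 0.000118, and adjusted p = 0.264 with an estimated correlation). Within that list Tdgf1 went from 836 ± 3.11 to 68.0 ± 1.89 CPM (log2 fold change -3.62, SE 0.2), and the measured levels of Pou5f1 were 1309.7 ± 22.9 and 526 ± 37.5 CPM. Of 18 germ cell specification genes, 4 were higher, 13 lower and 1 did not pass (median -1.42, camera adjusted p = 2.11e-05, and adjusted p = 0.172 with an estimated correlation). The 19 surface ectoderm and epithelial genes included 14 higher, 3 lower and 2 not passing (median 1.45, camera adjusted p = 0.00684, and adjusted p = 0.298 with an estimated correlation). Krt7, a simple epithelial keratin, rose from 2.34 ± 0.209 to 23.9 ± 1.61 CPM (log2 fold change 3.35, SE 0.19). That call ended over genes with under 10 percent of shared sequence. Trophoblast genes gave 13 higher, 3 lower and 3 not passing of 19 (median 1.77, camera adjusted p = 0.0171, and adjusted p = 0.0784 with an estimated correlation). Tpbpa, a spongiotrophoblast gene, went from 0 to 5.14 ± 0.305 CPM (at least 96.1-fold higher). Of 16 mesenchyme and fibroblast genes, 12 were higher, 0 lower and 4 did not pass (median 2.00, camera adjusted p = 0.00172, and adjusted p = 0.221 with an estimated correlation). The 32 imprinted genes included 19 higher, 7 lower and 6 not passing (median 0.85, camera adjusted p = 4.83e-05). Nnat, an imprinted proteolipid gene of the brain, rose from 3.85 ± 0.0158 to 396 ± 8.57 CPM (log2 fold change 6.68, SE 0.15). For these lists, adjusted over the list alone, the counts were the same except for Notch pathway (11 higher and 1 lower), surface ectoderm and epithelial (15 higher and 3 lower), trophoblast (14 higher and 3 lower) and mesenchyme and fibroblast (13 higher and 0 lower). At D8 12072 genes passed against D0, 6351 higher and 5721 lower, fewer than the 13336 at D6, after 9937 at D2 and 12337 at D4.

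At D0, the question was how TKO stem cells differed from WT stem cells before differentiation. Endoderm genes were higher in TKO at low to moderate levels: Sox17, an endoderm transcription factor, was 0.72 ± 0.0322 CPM in WT and 25.7 ± 0.687 in TKO (log2 fold change 5.14, SE 0.34, adjusted p = 3.83e-09). Cubn, an endocytic receptor of visceral endoderm, was 5.66 ± 1.69 and 149.9 ± 17 CPM (log2 fold change 4.73, SE 0.33). Ahead of them in fold were Ttr and Afp, at 0 in WT and below 1 CPM in TKO. Of 24 endoderm genes, 20 were higher, 0 lower and 4 did not pass (median 3.02, 2.91 with members at 0 set to their bound, camera adjusted p = 4.28e-23). Methylation-dependent germline genes gave 23 higher, 11 lower and 5 not passing of 39 (median 1.02, camera adjusted p = 2.87e-09, and adjusted p = 0.132 with an estimated correlation). Asz1, a germ cell gene of the piRNA pathway, was at 0 in WT and 1.93 ± 0.0332 CPM in TKO (at least 39.9-fold higher), and Fkbp6, another meiosis gene, at 0.52 ± 0.0977 and 15.6 ± 0.0206 CPM (log2 fold change 4.92, SE 0.2). Tuba3b (0.1 ± 0.00126 and 11.3 ± 0.486 CPM) shares 42.9% of its 31-mers with other genes, so its share of counts is uncertain. Dazl, a germ cell RNA-binding protein, was 4.98 ± 1.26 CPM in WT and 54.2 ± 6.2 in TKO (log2 fold change 3.44, SE 0.18, adjusted p = 1.41e-10). The 32 imprinted genes included 18 higher, 6 lower and 8 not passing (median 0.41, camera adjusted p = 0.00018). Plagl1, an imprinted zinc finger gene, was 0.32 ± 0.0952 and 33.0 ± 4.26 CPM (log2 fold change 6.66, SE 0.26), whereas Igf2, a growth factor of the same list, was 50.5 ± 5.69 and 2.12 ± 0.0515 CPM (log2 fold change -4.57, SE 0.25), with 88% of its 31-mers shared. Of 5 Xlr and X-inactivation genes, 4 were higher, 0 lower and 1 did not pass (median 7.97, 7.36 with members at 0 set to their bound, camera adjusted p = 2.44e-36). The Xlr genes that carried it led the whole comparison, with Xlr4a (at least 164-fold higher), Xlr5a (at least 153-fold higher) and Xlr5c (at least 110-fold higher) at 0 in WT, and these paralogs share 80.5%, 90.2% and 90.2% of their 31-mers. Next were Xlr4b, Dcdc2a (0.08 ± 0.0672 and 28.6 ± 1.37 CPM, log2 fold change 8.40, SE 0.35) and Magea4. The lowest were Xkrx (5.56 ± 0.975 and 0.14 ± 0.00503 CPM, log2 fold change -5.24, SE 0.8), Igf2, Lrrc15, Kif1a, an axonal motor, Mobp and Aspg.

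Dnmt3l, the catalytically inactive partner of the de novo enzymes, was higher in TKO at D0 (164 ± 31.1 and 537 ± 6.52 CPM, log2 fold change 1.71, SE 0.16), unlike the 3 Dnmt genes above. Those possible targets are among the 18 DNA methylation machinery genes and may carry calls of that list. Of the 18, 2 were higher, 8 lower and 8 did not pass (median -0.18, camera adjusted p = 0.000166). Y-linked genes gave 6 higher, 0 lower and 1 not passing of 7 (median 1.13, camera adjusted p = 2.68e-07). Zfy1 was 0.55 ± 0.129 and 8.49 ± 0.0545 CPM, with 54.6% of its 31-mers shared, and Kdm5d, a histone demethylase, 4.43 ± 0.308 and 17.2 ± 0.784 CPM (log2 fold change 1.96, SE 0.1). The 8 Rhox cluster genes included 4 higher, 1 lower and 3 not passing (median 2.46, 1.68 with members at 0 set to their bound, camera adjusted p = 0.0302, and adjusted p = 0.109 with an estimated correlation). Of 18 germ cell specification genes, 2 were higher, 6 lower and 10 did not pass (median -0.14, camera adjusted p = 0.0392, and adjusted p = 0.542 with an estimated correlation). Tfap2c, a transcription factor that leads this list, was lower in TKO (142 ± 5.6 and 25.2 ± 0.374 CPM, log2 fold change -2.49, SE 0.1). P53 target genes gave 10 higher, 2 lower and 10 not passing of 22 (median 0.25, camera adjusted p = 0.0302, and adjusted p = 0.636 with an estimated correlation). Cdkn1a, the cell cycle inhibitor p21, was 27.7 ± 2.18 and 62.4 ± 2.55 CPM (log2 fold change 1.17, SE 0.072). The last 3 calls rested on single libraries. The germ cell specification call ended without WT D0 replicate 1 (adjusted p = 0.201), TKO D0 replicate 1 (0.0512) or TKO D0 replicate 2 (0.125). The p53 call ended without WT D0 replicate 1 (0.449) or TKO D0 replicate 1 (0.0512). The Rhox call ended without WT D0 replicate 1 (0.0771), WT D0 replicate 2 (0.111), TKO D6 replicate 1 (0.0537) or TKO D6 replicate 2 (0.0513). With no low-count filter the germ cell specification and Rhox calls also ended, as did the p53 call over genes with under 10 percent of shared sequence and the germ cell specification call over protein-coding genes or length-scaled counts. For these lists, adjusted over the list alone, the counts were the same except for imprinted (18 higher and 7 lower), DNA methylation machinery (3 higher and 8 lower) and p53 target (12 higher and 2 lower). Core pluripotency genes showed no call (1 higher, 4 lower and 10 not passing of 15, adjusted p = 0.486), and the levels of Pou5f1 were 1312 ± 39.4 CPM in WT and 1309.7 ± 22.9 in TKO. At this day 7294 genes passed, 3598 higher and 3696 lower in TKO, of which 1274 and 856 differed at least 2-fold. A fit of the D0 groups alone passed 4877 of 16144 genes tested, so the larger total leans on the spread of the other days.

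At D2, when WT cells held most Dnmt3a and Dnmt3b, the 6 lowest genes in TKO were Xkrx (11.1 ± 1.43 and 0.51 ± 0.153 CPM, log2 fold change -4.41, SE 0.6), Dnmt3b, Dnmt3a, Tdrd1, a piRNA pathway gene, Dnmt1 and Bdh2. DNA methylation machinery genes gave 3 higher, 13 lower and 2 not passing of 18 (median -0.37, camera adjusted p = 5.63e-13). Endoderm genes stayed high in TKO, with Col4a2, a basement membrane collagen made in quantity by parietal endoderm, at 22.5 ± 0.476 CPM in WT and 438 ± 65.6 in TKO (log2 fold change 4.28, SE 0.19, adjusted p = 3.03e-11). Col4a1 was 49.8 ± 0.377 and 878 ± 142 CPM (log2 fold change 4.14, SE 0.21), behind Ttr and Afp, both below 2 CPM. Of 24 endoderm genes, 21 were higher, 0 lower and 3 did not pass (median 3.13, camera adjusted p = 1.46e-22). The 39 methylation-dependent germline genes included 27 higher, 5 lower and 7 not passing (median 1.44, camera adjusted p = 6.23e-23). Asz1 was 0.02 ± 0.0274 and 4.65 ± 0.618 CPM (count ratio 240, 95% counting interval 43.1 to 9490), and Fkbp6 1.12 ± 0.437 and 55.1 ± 2.73 CPM (log2 fold change 5.66, SE 0.17). Of 32 imprinted genes, 20 were higher, 3 lower and 9 did not pass (median 0.67, camera adjusted p = 1.15e-13). Dlk1, a Notch-like ligand that is imprinted, was 0.66 ± 0.157 and 12.9 ± 0.724 CPM (log2 fold change 4.30, SE 0.23), next to Plagl1 at 0.06 ± 0.0822 and 13.4 ± 2.32 CPM (count ratio 231, 95% counting interval 79.1 to 1120). Xlr and X-inactivation genes gave 4 higher, 0 lower and 1 not passing of 5 (median 6.60, camera adjusted p = 5.85e-42). Xlr5a, at 0 in WT, was the highest gene of the day (at least 219-fold higher), ahead of Xlr5b (at least 161-fold higher), Xlr4c (at least 132-fold higher) and Magea5 (at least 102-fold higher), which share 90.2%, 95.9%, 76.5% and 67.5% of their 31-mers. The 8 Rhox cluster genes included 5 higher, 0 lower and 3 not passing (median 2.28, camera adjusted p = 8.12e-05). Of 7 Y-linked genes, 6 were higher, 0 lower and 1 did not pass (median 1.88, camera adjusted p = 2.56e-12). These calls all held with an estimated correlation.

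Camera (preset correlation) placed neuron, anterior neural and Notch genes higher in TKO at D2, at low levels. Neural progenitor (13 higher, 5 lower and 12 not passing of 30, adjusted p = 0.0564) and glia genes (adjusted p = 0.841) had no call, but leaving out any 1 of 6 libraries gave the progenitor list a call (adjusted p from 0.0212 without WT D2 replicate 1 to 0.0475 without TKO D0 replicate 2). Neuron genes gave 21 higher, 0 lower and 9 not passing of 30 (median 0.89, camera adjusted p = 3.9e-07, and adjusted p = 0.258 with an estimated correlation). The leading members were Neurod4 and Nhlh2, at 0 in WT and under 1 CPM in TKO, and Nefm, a neurofilament gene, at 1.51 ± 0.82 and 16.2 ± 1.35 CPM (log2 fold change 3.49, SE 0.24). Of 17 anterior neural genes, 7 were higher, 1 lower and 9 did not pass (median 0.76, camera adjusted p = 0.037, and adjusted p = 0.0889 with an estimated correlation). The 12 Notch pathway genes included 6 higher, 0 lower and 6 not passing (median 0.84, camera adjusted p = 0.00102, and adjusted p = 0.0558 with an estimated correlation). Dll3 was 6.13 ± 0.593 and 17.3 ± 0.705 CPM (log2 fold change 1.51, SE 0.13). Retinoic acid pathway genes gave 5 higher, 1 lower and 7 not passing of 13 (median 0.84, camera adjusted p = 0.013, and adjusted p = 0.0878 with an estimated correlation). Of 15 neural crest genes, 5 were higher, 1 lower and 9 did not pass (median 0.44, camera adjusted p = 0.0348, and adjusted p = 0.0878 with an estimated correlation). Bmp and Tgfb target genes gave 9 higher, 1 lower and 5 not passing of 15 (median 0.48, camera adjusted p = 0.0239, and adjusted p = 0.308 with an estimated correlation). Besides DNA methylation machinery, camera placed naive, proliferation, and formative and primed genes lower in TKO. Of 18 naive pluripotency genes, 3 were higher, 9 lower and 6 did not pass (median -0.39, camera adjusted p = 0.0371, and adjusted p = 0.579 with an estimated correlation). Proliferation genes gave 0 higher, 8 lower and 12 not passing of 20 (median -0.20, camera adjusted p = 0.00349, and adjusted p = 0.468 with an estimated correlation). The 17 formative and primed pluripotency genes included 5 higher, 5 lower and 7 not passing (median -0.13, camera adjusted p = 0.000484, and adjusted p = 0.113 with an estimated correlation). Dnmt3b and Dnmt3a lead the last of them. Dppa5a of the naive list was 414 ± 39.7 and 193 ± 22.4 CPM with 57.2% of its 31-mers shared, and Fgf4 206 ± 6.49 and 104 ± 1.53 CPM (log2 fold change -0.99, SE 0.11). Leaving out 1 library ended the naive call (WT D2 replicate 2, adjusted p = 0.117, or TKO D2 replicate 2, 0.105), the anterior neural call (TKO D2 replicate 1, 0.0548), the neural crest call (TKO D2 replicate 2, 0.0546) and the Bmp and Tgfb call (WT D2 replicate 1, 0.0782). The anterior neural, formative and Bmp calls also ended over genes with under 10 percent of shared sequence, the formative call with no low-count filter, the anterior neural call without the D8 libraries and the naive call with the fry test (adjusted p = 0.0512). For the lists of this day, adjusted over the list alone, the counts were the same except for endoderm (22 higher and 0 lower), methylation-dependent germline (28 higher and 5 lower), imprinted (21 higher and 4 lower), neural progenitor (14 higher and 5 lower), neuron (23 higher and 0 lower), Notch pathway (8 higher and 0 lower) and retinoic acid pathway (6 higher and 1 lower). In all 6554 genes passed at D2, 3419 higher and 3135 lower, of which 1600 and 243 at least 2-fold.

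At D4, germline genes were higher in TKO. Dazl was 0.66 ± 0.0265 CPM in WT and 106 ± 12.3 in TKO (log2 fold change 7.32, SE 0.23, adjusted p = 1.81e-13), and Asz1 was at 0 in WT and 9.91 ± 0.423 CPM in TKO (at least 219-fold higher). Of 39 methylation-dependent germline genes, 31 were higher, 5 lower and 3 did not pass (median 2.66, camera adjusted p = 1.35e-56). Imprinted genes gave 18 higher, 8 lower and 6 not passing of 32 (median 0.28, camera adjusted p = 1.31e-05). Plagl1 was 2.16 ± 0.842 and 215 ± 4.05 CPM (log2 fold change 6.63, SE 0.18) and Nnat 5.58 ± 1.07 and 254 ± 9.3 CPM (log2 fold change 5.51, SE 0.14). Cdkn1c, an imprinted cell cycle inhibitor, was lower in TKO (139 ± 18.4 and 15.8 ± 0.203 CPM, log2 fold change -3.13, SE 0.098). The 30 neuron genes included 19 higher, 3 lower and 8 not passing (median 0.98, camera adjusted p = 5.47e-07, and adjusted p = 0.284 with an estimated correlation). Nefm was 4.56 ± 0.208 and 47.2 ± 0.895 CPM (log2 fold change 3.37, SE 0.17). Of 22 p53 target genes, 15 were higher, 0 lower and 7 did not pass (median 0.51, camera adjusted p = 1.54e-09, and adjusted p = 0.076 with an estimated correlation). Fas was 0.35 ± 0.0555 and 1.28 ± 0.108 CPM and Plk2 23.4 ± 2.12 and 56.7 ± 0.367 CPM (log2 fold change 1.28, SE 0.14). Bmp and Tgfb target genes gave 8 higher, 0 lower and 7 not passing of 15 (median 0.59, camera adjusted p = 0.000422, and adjusted p = 0.161 with an estimated correlation). Lefty2, a Nodal inhibitor, led it at 2.17 ± 1.46 and 20.9 ± 6.09 CPM (log2 fold change 3.27, SE 0.31), with 17.8% of its 31-mers shared. The 10 Shh pathway genes included 6 higher, 0 lower and 4 not passing (median 0.65, camera adjusted p = 0.00178, and adjusted p = 0.076 with an estimated correlation). Of 24 endoderm genes, 14 were higher, 1 lower and 9 did not pass (median 0.91, camera adjusted p = 0.000168, and adjusted p = 0.336 with an estimated correlation). Levels in that list were low, with Sox17 at 0.2 ± 0.0261 and 1.61 ± 0.25 CPM. Rhox cluster genes gave 5 higher, 0 lower and 3 not passing of 8 (median 3.45, 2.75 with members at 0 set to their bound, camera adjusted p = 8.83e-08). The 5 Xlr and X-inactivation genes included 4 higher, 0 lower and 1 not passing (median 7.65, camera adjusted p = 2.91e-55). Of 7 Y-linked genes, 6 were higher, 0 lower and 1 did not pass (median 3.93, camera adjusted p = 1.5e-29). Formative and primed pluripotency genes gave 5 higher, 8 lower and 4 not passing of 17 (median -0.21, camera adjusted p = 1.19e-05, and adjusted p = 0.076 with an estimated correlation). The 18 DNA methylation machinery genes included 4 higher, 5 lower and 9 not passing (median 0.00, camera adjusted p = 4.26e-06). The mean of the methylation list was -0.37 against that median of 0, and its call ended with no low-count filter. The highest genes were Xlr4a (at least 342-fold higher, 80.5% shared), Asz1, Xlr4c, Rhox2a, Tktl2 (at least 148-fold higher), a transketolase-like gene of testis, and Xlr3a. The lowest were Xkrx, H2-Q6, Fezf2, a forebrain factor (7.6 ± 0.305 and 0.51 ± 0.0137 CPM, log2 fold change -3.90, SE 0.3), Egr2, a hindbrain factor, Dnmt3a and Dnmt3b, with H2-Q6 sharing 51.8% of its 31-mers. For these lists, adjusted over the list alone, the counts were the same except for methylation-dependent germline (32 higher and 5 lower), imprinted (18 higher and 10 lower), neuron (21 higher and 4 lower), p53 target (18 higher and 1 lower) and Shh pathway (7 higher and 0 lower). Of 5259 genes that passed at D4, 2804 were higher and 2455 lower, with 1029 and 396 at least 2-fold, and without TKO D4 replicate 2 the total was 3355.

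At D6 the genotypes parted in germline, pluripotency and epithelial genes. Dazl stood at 0.09 ± 0.129 CPM in WT and 262 ± 42.9 in TKO (log2 fold change 11.37, SE 0.3), and Tuba3b and Asz1 at 0 in WT (at least 1080-fold higher and at least 417-fold higher, with 42.9% of Tuba3b shared). Of 39 methylation-dependent germline genes, 36 were higher, 0 lower and 3 did not pass (median 5.47, 5.10 with members at 0 set to their bound, camera adjusted p = 4.41e-88). Rhox cluster genes gave 6 higher, 0 lower and 2 not passing of 8 (median 5.04, 3.75 with members at 0 set to their bound, camera adjusted p = 3.29e-09). Genes of the pluripotent state were higher in TKO. Pou5f1 was 4.4 ± 1.92 and 49.8 ± 7.89 CPM (log2 fold change 3.49, SE 0.29, adjusted p = 3.85e-08). Nr0b1, an orphan nuclear receptor of naive cells, was 0.09 ± 0.0389 and 3.23 ± 0.551 CPM (log2 fold change 5.04, SE 0.54). The 18 naive pluripotency genes included 16 higher, 0 lower and 2 not passing (median 2.78, camera adjusted p = 2.94e-14). Of 15 core pluripotency genes, 10 were higher, 4 lower and 1 did not pass (median 2.43, camera adjusted p = 9.68e-05, and adjusted p = 0.227 with an estimated correlation). Germ cell specification genes gave 13 higher, 1 lower and 4 not passing of 18 (median 1.37, camera adjusted p = 5.27e-06, and adjusted p = 0.098 with an estimated correlation). The 19 surface ectoderm and epithelial genes included 18 higher, 0 lower and 1 not passing (median 1.64, camera adjusted p = 1.48e-18). Krt5 and Krt14, keratins of stratified epithelium, were under 1 CPM, and Esrp1, an epithelial splicing factor, was 2.53 ± 0.0684 and 13.6 ± 2.81 CPM (log2 fold change 2.43, SE 0.19). Of 19 trophoblast genes, 14 were higher, 2 lower and 3 did not pass (median 2.15, camera adjusted p = 8.38e-06). Hand1, a factor of trophoblast and mesoderm, was 0.13 ± 0.0527 and 1.93 ± 0.103 CPM (log2 fold change 3.88, SE 0.47). Endoderm genes gave 17 higher, 1 lower and 6 not passing of 24 (median 1.85, camera adjusted p = 4.15e-06, and adjusted p = 0.21 with an estimated correlation). Apob was 0.11 ± 0.0741 and 1.24 ± 0.0328 CPM and Gata6 0.98 ± 0.498 and 10.5 ± 1.08 CPM (log2 fold change 3.39, SE 0.33), behind Afp at 1.16 ± 0.0899 CPM in TKO. The 5 Xlr and X-inactivation genes included 5 higher and 0 lower (median 9.63, 8.96 with members at 0 set to their bound, camera adjusted p = 1.17e-36). Of 7 Y-linked genes, 6 were higher, 0 lower and 1 did not pass (median 4.39, camera adjusted p = 6.43e-28). Zfy1 was at 0 in WT and 3.81 ± 0.313 CPM in TKO, Uba1y 0.63 ± 0.0395 and 60.4 ± 9.21 CPM with 66.7% of its 31-mers shared, and Kdm5d 2.43 ± 0.353 and 141 ± 0.296 CPM (log2 fold change 5.86, SE 0.1). Imprinted genes gave 19 higher, 9 lower and 4 not passing of 32 (median 0.59, camera adjusted p = 0.00356). Grb10, an imprinted growth inhibitor, was 624 ± 9.58 and 27.2 ± 0.843 CPM (log2 fold change -4.52, SE 0.14).

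Neural genes at D6 went both ways in TKO. Of 30 neuron genes, 24 were higher, 0 lower and 6 did not pass (median 0.76, camera adjusted p = 8.55e-10, and adjusted p = 0.174 with an estimated correlation). Nefm was 23.6 ± 1.89 and 463 ± 116 CPM (log2 fold change 4.29, SE 0.15), Snap25, a synaptic protein, 5.95 ± 0.502 and 20.8 ± 2.84 CPM (log2 fold change 1.80, SE 0.13), and the tubulin Tubb3 344 ± 1.79 and 524 ± 102 CPM (log2 fold change 0.61, SE 0.18). The Tubb3 call ended without WT D6 replicate 1 (adjusted p = 0.0584), WT D6 replicate 2 (0.062) or TKO D6 replicate 2 (0.172). Neural progenitor genes gave 5 higher, 14 lower and 11 not passing of 30 (median -0.26, camera adjusted p = 0.00185, and adjusted p = 0.185 with an estimated correlation). Neurog2, a proneural factor, was lower (15.4 ± 3.11 and 4.95 ± 0.197 CPM, log2 fold change -1.64, SE 0.25), as was Zic1 (11.4 ± 0.912 and 3.99 ± 0.314 CPM, log2 fold change -1.52, SE 0.18). The 17 anterior neural genes included 11 higher, 2 lower and 4 not passing (median 1.06, 0.94 with members at 0 set to their bound, camera adjusted p = 0.00051). En2, a midbrain factor, was 1.41 ± 0.069 and 17.9 ± 2.53 CPM (log2 fold change 3.66, SE 0.14). The 15 Bmp and Tgfb target genes included 10 higher, 2 lower and 3 not passing (median 0.70, camera adjusted p = 0.00466, and adjusted p = 0.211 with an estimated correlation). Of 14 Fgf and Mapk target genes, 8 were higher, 0 lower and 6 did not pass (median 0.53, camera adjusted p = 0.00152, and adjusted p = 0.185 with an estimated correlation). Interferon response genes gave 8 higher, 2 lower and 15 not passing of 25 (median 0.97, camera adjusted p = 0.0227, and adjusted p = 0.211 with an estimated correlation). The 16 stress and unfolded protein response genes included 8 higher, 0 lower and 8 not passing (median 0.52, camera adjusted p = 0.0214, and adjusted p = 0.538 with an estimated correlation). Mx1, an antiviral GTPase, was 1.32 ± 0.276 and 30.3 ± 0.213 CPM (log2 fold change 4.51, SE 0.17), and Etv4, an Fgf-induced factor, 0.56 ± 0.147 and 5.26 ± 0.052 CPM (log2 fold change 3.24, SE 0.51). The interferon call ended without TKO D6 replicate 1 (adjusted p = 0.0606) and the stress call without WT D6 replicate 1 (adjusted p = 0.0782). Of 18 DNA methylation machinery genes, 3 were higher, 7 lower and 8 did not pass (median -0.07, camera adjusted p = 0.00131). That call ended with no low-count filter. The lowest genes in TKO were Kcnk9, a potassium channel (25.7 ± 1.89 and 0.72 ± 0.0294 CPM, log2 fold change -5.16, SE 0.21), Grb10, Pdgfd, Pcdh17, a protocadherin (57.8 ± 2.82 and 3.05 ± 0.703 CPM, log2 fold change -4.26, SE 0.17), Dnmt3a and St8sia4. For the lists of D6, adjusted over the list alone, the counts were the same except for endoderm (18 higher and 1 lower), neuron (26 higher and 1 lower), anterior neural (11 higher and 3 lower), interferon response (9 higher and 2 lower) and stress and unfolded protein response (9 higher and 0 lower). The test passed 7654 genes at D6, 3883 higher and 3771 lower, with 2223 and 471 at least 2-fold.

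At D8 neural genes were lower and pluripotency genes higher in TKO. Mapt, the neuronal tau protein, was 227 ± 12.8 CPM in WT and 28.5 ± 0.993 in TKO (adjusted p = 3.52e-13), and Neurod4, a neuronal differentiation factor, 25.5 ± 3.45 and 2.9 ± 0.538 CPM (log2 fold change -3.13, SE 0.2). Of 30 neuron genes, 1 was higher and 29 lower (median -2.07, camera adjusted p = 3.49e-20). Neural progenitor genes gave 2 higher, 26 lower and 2 not passing of 30 (median -1.51, camera adjusted p = 6.63e-18). Nkx6-1, a ventral neural tube factor, was 87.8 ± 14.3 and 8.02 ± 1.12 CPM (log2 fold change -3.46, SE 0.17) and Neurog2 24.9 ± 3.14 and 2.68 ± 0.0274 CPM (log2 fold change -3.22, SE 0.27). Of the neural markers fixed in advance, Pax6 was 146 ± 5.5 and 41.2 ± 0.497 CPM (log2 fold change -1.82, SE 0.063) and Sox1 179.6 ± 5.49 and 121 ± 7.65 CPM (log2 fold change -0.57, SE 0.092). Nes was 534 ± 29.2 and 228 ± 4.78 CPM (log2 fold change -1.22, SE 0.081) and Tubb3 1287 ± 16.5 and 314 ± 1.3 CPM (log2 fold change -2.03, SE 0.19). The 12 Notch pathway genes included 1 higher, 7 lower and 4 not passing (median -0.74, camera adjusted p = 0.00262, and adjusted p = 0.0639 with an estimated correlation). Hes5 was 79.1 ± 0.641 and 18.5 ± 1.13 CPM (log2 fold change -2.10, SE 0.12). Of 10 Shh pathway genes, 1 was higher, 7 lower and 2 did not pass (median -1.05, camera adjusted p = 0.0212, and adjusted p = 0.183 with an estimated correlation). Posterior Hox and Cdx genes gave 10 higher, 9 lower and 6 not passing of 25 (median 0.39, camera adjusted p = 0.00766, and adjusted p = 0.211 with an estimated correlation). Their mean was -0.02 and camera placed the list lower, against the positive median, and the call ended with no low-count filter and over genes with under 10 percent of shared sequence. Hoxb2 (42.2 ± 1.29 and 1.55 ± 0.317 CPM, log2 fold change -4.75, SE 0.17) and Hoxa2 (61.1 ± 0.0877 and 2.37 ± 0.0131 CPM, log2 fold change -4.69, SE 0.14), which pattern the hindbrain, were lower, with 13.7% of the 31-mers of Hoxa2 shared.

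Pou5f1 was 12.5 ± 7.13 CPM in WT and 526 ± 37.5 in TKO at D8 (log2 fold change 5.38, SE 0.26, adjusted p = 8.13e-12). Nanog was 4.78 ± 1.33 and 81.0 ± 5.4 CPM (log2 fold change 4.08, SE 0.22) and Zfp42 2.63 ± 1.64 and 65.9 ± 1.74 CPM (log2 fold change 4.63, SE 0.26), with 11% and 14.6% of the 31-mers of the last pair shared. Of 15 core pluripotency genes, 14 were higher and 1 lower (median 4.43, camera adjusted p = 1.34e-13). Utf1, a chromatin factor of stem cells, was 3.64 ± 1.72 and 154 ± 15.4 CPM (log2 fold change 5.39, SE 0.23), behind Lefty2 at 0.82 ± 0.362 and 74.2 ± 3.88 CPM (log2 fold change 6.47, SE 0.34, 17.8% shared). The 18 naive pluripotency genes included 15 higher, 2 lower and 1 not passing (median 3.19, camera adjusted p = 5.63e-08, and adjusted p = 0.103 with an estimated correlation). Formative and primed pluripotency genes gave 14 higher, 2 lower and 1 not passing of 17 (median 2.49, camera adjusted p = 2.57e-06). Fgf5, a marker of the primed epiblast, was 1.65 ± 0.724 and 31.3 ± 0.68 CPM (log2 fold change 4.24, SE 0.23). The 18 germ cell specification genes included 15 higher, 2 lower and 1 not passing (median 2.11, camera adjusted p = 1.75e-05, and adjusted p = 0.103 with an estimated correlation). Of 19 surface ectoderm and epithelial genes, 15 were higher, 0 lower and 4 did not pass (median 1.73, camera adjusted p = 7.02e-09). Epcam, an epithelial adhesion molecule, was 8.69 ± 0.338 and 145 ± 11.3 CPM (log2 fold change 4.06, SE 0.13), behind Krt14 at 2.71 ± 0.322 CPM in TKO (25.1% shared). Methylation-dependent germline genes gave 33 higher, 2 lower and 4 not passing of 39 (median 5.45, 5.38 with members at 0 set to their bound, camera adjusted p = 1.89e-32). Dazl was 0.16 ± 0.0974 and 111 ± 2.45 CPM (log2 fold change 9.40, SE 0.28). The 5 Xlr and X-inactivation genes included 5 higher and 0 lower (median 7.97, 7.79 with members at 0 set to their bound, camera adjusted p = 9.04e-15). Of 7 Y-linked genes, 7 were higher and 0 lower (median 4.52, camera adjusted p = 6.78e-10). Rhox cluster genes gave 7 higher, 0 lower and 1 not passing of 8 (median 3.24, 3.03 with members at 0 set to their bound, camera adjusted p = 0.00856, and adjusted p = 0.0526 with an estimated correlation). The 20 proliferation genes included 17 higher, 1 lower and 2 not passing (median 0.87, camera adjusted p = 2.57e-06, and adjusted p = 0.198 with an estimated correlation). Ccne1, the cyclin of S phase entry, was 43.4 ± 1.75 and 127 ± 9.73 CPM (log2 fold change 1.54, SE 0.11). Of 20 glycolysis and hypoxia genes, 15 were higher, 1 lower and 4 did not pass (median 1.10, camera adjusted p = 0.00395, and adjusted p = 0.521 with an estimated correlation). Pdk1 was 7.75 ± 0.583 and 100.4 ± 8.21 CPM (log2 fold change 3.69, SE 0.15). Stress and unfolded protein response genes gave 14 higher, 0 lower and 2 not passing of 16 (median 0.85, camera adjusted p = 0.00944, and adjusted p = 0.521 with an estimated correlation). The 22 p53 target genes included 20 higher, 1 lower and 1 not passing (median 0.64, camera adjusted p = 0.0031, and adjusted p = 0.38 with an estimated correlation). The highest genes were Pramel3 (at least 349-fold higher), Mageb4 (at least 257-fold higher), Fthl17c (at least 256-fold higher), Lnp1 (at least 225-fold higher), Xlr5a and Xlr5b, all at 0 in WT, and except for Lnp1 they share 59.3% or more of their 31-mers with other genes. The lowest were Kcnk9 (36.3 ± 1.09 and 0.4 ± 0.0831 CPM, log2 fold change -6.52, SE 0.23), Fstl5, Pcdh17, Spock3, Nap1l3 and Slitrk1, genes of neurons.

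The other lists had no camera call at D8. Lists of other cell types among them were endoderm (9 higher, 4 lower and 11 not passing of 24, adjusted p = 0.737) and trophoblast (12 higher, 1 lower and 6 not passing of 19, adjusted p = 0.155). Hand1 was 0.45 ± 0.00411 and 4.53 ± 0.169 CPM (log2 fold change 3.31, SE 0.36). Imprinted genes split evenly (14 higher, 15 lower and 3 not passing of 32, adjusted p = 0.737). Igf2 was at 308 ± 27.9 and 9.7 ± 2.2 CPM (88% shared), Plagl1 at 5.14 ± 0.827 and 91.3 ± 5.48 CPM (log2 fold change 4.15, SE 0.16) and Nnat at 29.1 ± 3.44 and 396 ± 8.57 CPM (log2 fold change 3.77, SE 0.12). Neural lists without a call were anterior neural (5 higher and 7 lower of 17, adjusted p = 0.737), glia (3 higher and 4 lower of 11, adjusted p = 0.537) and neural crest (5 higher and 5 lower of 15, adjusted p = 0.446). Other such lists were DNA methylation machinery (7 higher and 8 lower of 18, adjusted p = 0.568), primitive streak and mesoderm (7 higher and 5 lower of 20, adjusted p = 0.716), mesenchyme and fibroblast (2 higher and 7 lower of 16, adjusted p = 0.33), 2-cell-like (1 higher and 1 lower of 14, adjusted p = 0.737) and interferon response (10 higher and 2 lower of 25, adjusted p = 0.201). Otx2, a forebrain and epiblast factor, led the anterior list and was higher in TKO (9.28 ± 2.07 and 66.3 ± 7.25 CPM, log2 fold change 2.83, SE 0.15), while Slc1a2, a glutamate transporter of glia, was lower (81.3 ± 2.5 and 16.7 ± 0.61 CPM, log2 fold change -2.28, SE 0.11). Bst2 and Mx1 of the interferon list were higher, Mx1 at 1.78 ± 0.574 and 21.4 ± 0.494 CPM (log2 fold change 3.58, SE 0.16). Among pathway lists there was no call for Wnt target (7 higher and 4 lower of 15, adjusted p = 0.435), retinoic acid pathway (7 higher and 5 lower of 13, adjusted p = 0.737), Bmp and Tgfb target (8 higher and 2 lower of 15, adjusted p = 0.267), Fgf and Mapk target (9 higher and 3 lower of 14, adjusted p = 0.297) or mitochondrially encoded (7 higher and 1 lower of 13, adjusted p = 0.579). Median, mean and camera direction differed in sign for DNA methylation machinery (median -0.08, mean 0.19, camera lower), anterior neural (median 0.02, mean -0.05, camera lower), glia (median -0.33, mean 0.13, camera lower), neural crest (median 0.02, mean 0.03, camera lower), primitive streak and mesoderm (median 0.43, mean 0.45, camera lower), imprinted (median -0.08, mean 0.05, camera lower) and retinoic acid pathway genes (median 0.63, mean 0.74, camera lower). For the lists of D8, adjusted over the list alone, the counts were the same except for Notch pathway (2 higher and 7 lower), Shh pathway (1 higher and 8 lower), interferon response (9 higher and 2 lower), retinoic acid pathway (8 higher and 5 lower) and Fgf and Mapk target (10 higher and 3 lower). No library left out changed a list call at this day. Of the 18555 genes tested, 12532 passed at D8, 6637 higher and 5895 lower in TKO, with 3190 and 2407 at least 2-fold.

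**Figure D3:**
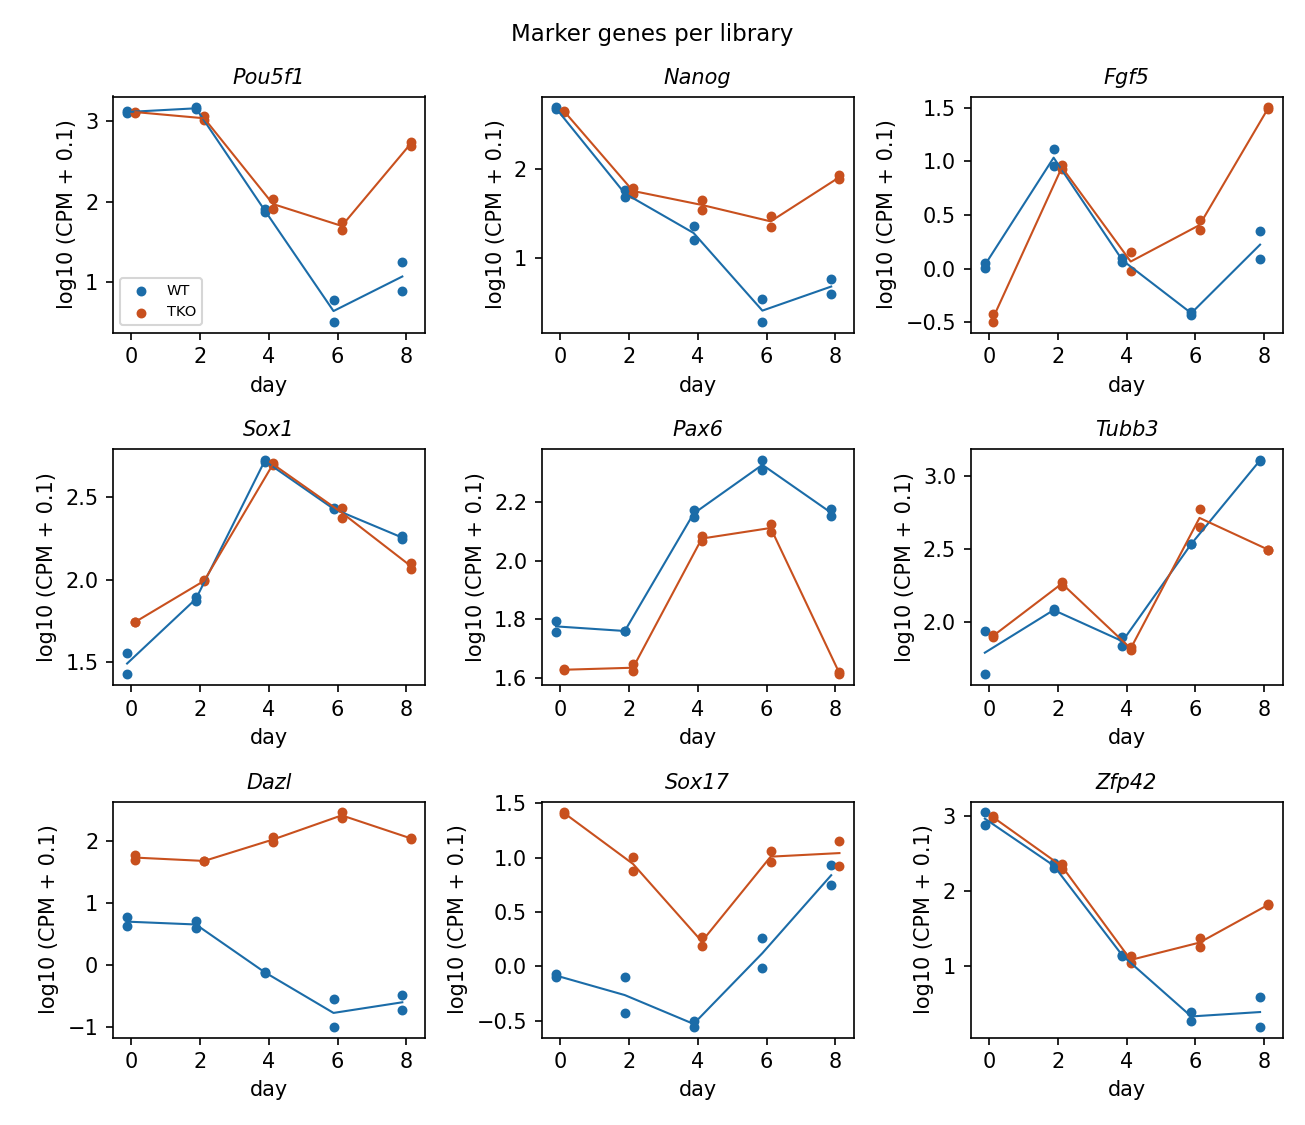
Levels of 9 marker genes per library by day, as log10 of CPM plus 0.1, with lines through the means of 2 libraries per group. In TKO, Pou5f1, Nanog, Zfp42 and Fgf5 are higher at D8 than at D6.

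Whether the change from D0 to D8 itself differed between the genotypes was tested with the interaction term. The change of pluripotency and germline genes lay higher in TKO than in WT, and that of neural genes lower. Core pluripotency genes gave 14 higher, 0 lower and 1 not passing of 15 (median 4.84, camera adjusted p = 5.01e-21). The 18 naive pluripotency genes included 15 higher, 2 lower and 1 not passing (median 3.67, camera adjusted p = 2.14e-12). Fgf4 was at 48.9 ± 5.12 CPM in TKO at D8 against 0.6 ± 0.164 in WT (log2 fold change 6.40, SE 0.25, adjusted p = 4.91e-12). Of 17 formative and primed pluripotency genes, 14 were higher, 1 lower and 2 did not pass (median 2.12, camera adjusted p = 1.87e-05, and adjusted p = 0.071 with an estimated correlation). Methylation-dependent germline genes gave 33 higher, 1 lower and 5 not passing of 39 (median 4.47, 4.07 with members at 0 set to their bound, camera adjusted p = 6.3e-24). Mov10l1, a piRNA helicase, went from 9.05 ± 1.26 to 0.09 ± 0.0794 CPM in WT and from 13.05 ± 2.87 to 28.9 ± 1.71 in TKO (log2 fold change 7.77, SE 0.45). The 18 germ cell specification genes included 15 higher, 1 lower and 2 not passing (median 2.55, camera adjusted p = 5.67e-10). Of 30 neural progenitor genes, 2 were higher, 18 lower and 10 did not pass (median -1.36, -1.41 with members at 0 set to their bound, camera adjusted p = 2.34e-11). Neuron genes gave 0 higher, 24 lower and 6 not passing of 30 (median -1.91, camera adjusted p = 1.08e-12, and adjusted p = 0.115 with an estimated correlation). Nefl, a neurofilament gene, went from 20.8 ± 3.07 to 1067 ± 40.9 CPM in WT and from 43.4 ± 0.895 to 160.0 ± 3.02 in TKO, with 32.2% of its 31-mers shared, after Lhx1 and Ebf3. The 24 endoderm genes included 2 higher, 19 lower and 3 not passing (median -2.93, -2.81 with members at 0 set to their bound, camera adjusted p = 3.26e-08, and adjusted p = 0.16 with an estimated correlation). Foxa2, which acts in endoderm and floor plate, was 0.35 ± 0.0864 and 14.2 ± 0.162 CPM in WT and 7.75 ± 1.06 and 7.82 ± 1.81 in TKO (log2 fold change -5.29, SE 0.31). Of 19 surface ectoderm and epithelial genes, 12 were higher, 2 lower and 5 did not pass (median 1.54, 2.38 with members at 0 set to their bound, camera adjusted p = 6.34e-09). Imprinted genes gave 5 higher, 16 lower and 11 not passing of 32 (median -0.47, camera adjusted p = 0.00329). Dlk1 was 0.73 ± 0.26 and 12.9 ± 0.106 CPM in WT and 3.54 ± 0.326 and 5.74 ± 0.236 in TKO (log2 fold change -3.45, SE 0.3). The 20 proliferation genes included 16 higher, 0 lower and 4 not passing (median 0.84, camera adjusted p = 9.24e-07, and adjusted p = 0.196 with an estimated correlation). Of 20 glycolysis and hypoxia genes, 13 were higher, 0 lower and 7 did not pass (median 1.16, camera adjusted p = 0.00172, and adjusted p = 0.499 with an estimated correlation). Y-linked genes gave 6 higher, 0 lower and 1 not passing of 7 (median 2.56, camera adjusted p = 0.000303). For these lists, adjusted over the list alone, the counts were the same except for methylation-dependent germline (34 higher and 1 lower), neural progenitor (2 higher and 19 lower), imprinted (5 higher and 17 lower) and glycolysis and hypoxia (14 higher and 0 lower). The interaction passed for 9695 genes, 5445 with a higher and 4250 with a lower change in TKO, and a joint test over all 4 later days passed for 12792, or 7253 without the D8 libraries.

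**Figure D4:**
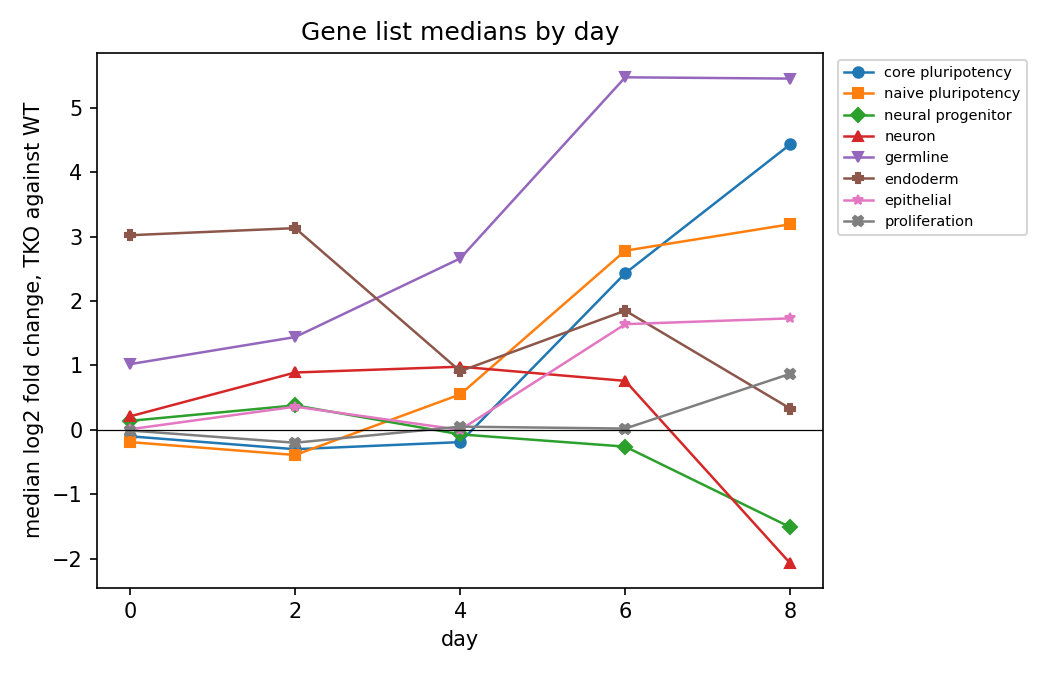
Median log2 fold change of TKO against WT by day for 8 gene lists, with each point the median over the measured members. The core pluripotency median is 4.43 and the neuron median -2.07 at D8.

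How alike the genotype difference was from day to day was read across the 18555 genes, which are not independent replicates. The Pearson correlation of the log2 fold changes was 0.619 between D6 and D8 and 0.573 between D4 and D6, and 0.244 between D2 and D8, and the median over all pairs of days was 0.439, or 0.241 with no low-count filter. Of genes called at D6 and D8, 2454 were higher at both (1388.9 expected by chance), 2234 lower (1198.1 expected) and 1352 went opposite ways. For D2 and D8 they were 1515 (1223 expected), 1222 (996) and 2362. At all 5 days, 261 genes were at least 2-fold higher in TKO and 12 at least 2-fold lower, out of 5168 and 3345 at any day. By chromosome, camera called the X chromosome at D0, D2, D4 and D6 (adjusted p = 0.00022, 8.8e-05, 8.22e-08 and 7.03e-05), but not at D8 (adjusted p = 0.131), and the Y chromosome at all 5 days, and whether the days differ was not tested. Over expressed X genes the median log2 fold change stayed between -0.059 and 0.054. Eif2s3y, a Y-linked gene named after its values were seen, was 99.9 ± 1.5 CPM in WT and 97.6 ± 4.95 in TKO at D0, so Y transcripts were present in both genotypes. T, the streak factor brachyury, was low throughout, at most 4.33 ± 2.62 CPM in TKO D8.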

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

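The interaction test was planned, while every test of an explanation below, and the reading of unmatched transcripts, was chosen after the result was seen.

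The change from D0 to D8 differed between TKO and WT, by a test of the difference itself, for 9695 genes, and the time course at any later day differed for 12792. The change of pluripotency lists lay higher in TKO, with a median log2 difference of 4.84 for core, 3.67 for naive and 2.12 for formative and primed genes, as did methylation-dependent germline (4.47), germ cell specification (2.55) and Y-linked genes (2.56). Surface ectoderm and epithelial (1.54, and 2.38 with members at 0 set to their bound), glycolysis and hypoxia (1.16) and proliferation genes (0.84) also changed upward relative to WT. Neuron (-1.91), neural progenitor (-1.36), endoderm (-2.93) and imprinted genes (-0.47) changed downward relative to WT. With an estimated correlation the calls ended for formative and primed (adjusted p = 0.071), glycolysis and hypoxia (0.499), proliferation (0.196), neuron (0.115) and endoderm genes (0.16). Of the 24 endoderm genes 16 rose by D8 in WT, while 20 were already higher in TKO than in WT at D0.

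Single genes at the upper end of the interaction were Mov10l1 (7.773, SE 0.45), Tex101 (7.402, SE 0.78), a sperm surface protein, and Tmem54 (7.249, SE 0.83), with Stra8 (8.285) and Mageb4 (7.651) at 0 in WT D8 and so at least 27.5-fold and 18.3-fold higher in their change, and 59.3% of Mageb4 shared. At the lower end was the neural gene Fstl5 (-9.524, SE 0.72). Others rest on 1 to 3 counts in a group and have 95% counting intervals on the log2 scale of 1.96 to 14.64 for the protease inhibitor Slpi (7.209), -14.0 to -6.21 for Nkx6-1 (-8.379), -13.97 to -6.19 for Asxl3 (-8.356), -13.91 to -6.13 for Otp (-8.329) and -10.12 to -6.30 for Pcdh17 (-7.754). Fitted values of genes with so few counts depend on the prior count. Slpi did not pass without WT D0 replicate 2 (4.046, adjusted p = 0.955), nor Otp without TKO D0 replicate 1 (-2.564, adjusted p = 0.933).

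Among 1239 transcripts that match no gene of the annotation and stayed out of the comparisons, 147 were at least 2-fold higher in TKO than in WT at D8 and 45 at least 2-fold lower. ENSMUST00000231162.1 was at 11.4 ± 0.51 CPM in WT and 979 ± 1.95 CPM in TKO.

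Pluripotency genes were higher in TKO than in WT at D8, with 14 of 15 core genes higher and a median log2 fold change of 4.43. TKO cells of D0 mixed into both TKO D8 samples are argued against as the whole cause, because 121 genes of at least 50 CPM at TKO D0 and at most a 10th of that at TKO D6 stood at a median of 16.8% of their D0 level, 76 of them under 0.5 times the 40.2% of Pou5f1, such as Esrrb at 5.63%, though Utf1 stood at 56.8% and Nodal at 65.3%. TKO cells of D2 are argued against less strongly, with a median of 29.3% over 65 genes and 25 of them under 0.5 times the 47.9% of Pou5f1, such as Dnmt3l at 7.51%, while Utf1 at 44%, L1td1 at 49% and Nodal at 68.9% go with such cells. Reads shared with paralogs or pseudogenes are argued against by a median of 3.34 over the 10 core members with under 10% shared 31-mers, 9 of them higher. A smaller share of such cells, a mix of several earlier days, cells in another pluripotent state and a difference between the WT and TKO lines apart from the knockout stay open, since the design gives genotype and line together.

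Neural genes were lower in TKO than in WT at D8. Dilution of the same neural cells as the whole cause is argued against only weakly, partly by Nefm (1.04). It would lower all neural genes off at D0 alike. Log2 fold changes of 41 such genes had a median of -2.13 and an SD of 0.92 (0.78 without Nefm) against a median SE of 0.13. Only 5, Nefm included, lay more than 1 from the median. A few genes taking most of the counts are argued against by the 10 highest genes holding at most 8.04% of a library, where 76.2% would be needed. A delay as the whole cause is argued against for neuron genes by 24 of 30 being higher in TKO than in WT at D6 (camera adjusted p = 8.55e-10, and adjusted p = 0.174 with an estimated correlation), and for neural progenitor genes, of which 14 were lower and 5 higher at D6, by 24 of 30 falling in TKO from D6 to D8, where at most 11 of 30 fell in any step of the WT course. Dilution as a part of the fall, neural cells of other composition and a line difference apart from the knockout stay open.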

How the results depend on the processing

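Protein-coding genes alone, genes with under 10% shared 31-mers and the fit without the D8 libraries were added after the data were seen, and all other alternatives were planned. Counts of changed genes, of called lists and of chromosomes stayed within 1.5 times under relative log expression scaling. So did those available with length-scaled TPM counts, protein-coding genes, genes with little shared sequence and a fit of the compared groups alone. That last fit gave 4877 genes for TKO against WT at D0, where the main fit gave 7294. These counts and the median correlation between days made 18 results. Under relative log expression scaling the correlation stayed within 0.005, the SD between single-replicate values. A change of at least 2-fold moved 14 counts. For TKO against WT they were 2130 at D0, 1843 at D2, 1425 at D4, 2694 at D6 and 5597 at D8. Against D0 they were 3439, 5643, 7213 and 8635 in WT and 3365, 5974, 7137 and 5597 in TKO at D2, D4, D6 and D8, and 4653 for the interaction. Fewer genes can pass such a threshold by its construction.

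At D4, TKO against WT gave 5259 genes, 3236 at an adjusted p under 0.01, and from 3355 without TKO D4 replicate 2 to 5973 without WT D0 replicate 2 when libraries were left out. The joint test fell from 12792 to 7253 genes without the D8 libraries, which removes 1 of its 4 days. The median correlation of the genotype difference between days was 0.439, with 0.446 by DESeq2 and 0.241 with no low-count filter, where the cause was not tested. Genes with little shared sequence shifted the median of all genes by -0.105 at D8 against D0 in WT, by -0.102 at D6 in WT and by -0.106 at D6 in TKO.

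Of the list tests, 116 passed, against 55 with an estimated correlation and 211 with fry, and the cause was not tested. With no low-count filter 25 list calls were gained and 9 lost, with length-scaled counts 8 gained and 1 lost, and with relative log expression 2 lost. Leaving out a library kept 5371 of the repeated list results, gained 43 calls and lost 25. One result reversed: the glycolysis and hypoxia list at D0 had a mean log2 fold change from -0.39 without WT D0 replicate 2 to 0.47 without WT D0 replicate 1 (adjusted p = 2.04e-05), so no direction is claimed for it at D0. Of the 133 named gene results, those for Tubb3 at D6 and for Slpi and Otp in the interaction lost their call when a library was left out, and none changed direction under the alternatives run.

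The labels do not say that replicate numbers mark a shared day or batch, and the samples are not treated as paired. Deviations from the group means correlated between -0.24 and 0.28 over 45 pairs of groups, with a median of 0.02. The correlation was over 0.1 in 8 pairs, such as TKO D0 with TKO D2 (0.242) and TKO D4 (0.207), TKO D2 with TKO D4 (0.235) and WT D6 with TKO D6 (0.277), and under -0.1 in 5. With a replicate block 7223 genes passed in TKO against WT at D0, 6529 at D2, 5200 at D4, 7596 at D6 and 12482 at D8. Of the lists it ended the anterior neural call at D2 (adjusted p = 0.0554), brought in neural crest in WT (0.0499) and formative and primed in TKO (0.0482) at D8 against D0, and changed no other call.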

Other observations

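All results in this part were chosen after the data were seen. Families of at least 10 genes with a common name stem, 216 in all, were tested with camera beside the lists. At D8, 50 of 51 Rpl genes were higher in TKO and 0 lower (median log2 fold change 1.00, adjusted p = 2.54e-19). Of 46 Rps genes, not all ribosomal, 39 were higher and 3 lower (0.96, adjusted p = 1.73e-12). All 10 Mcm genes were higher (0.87, adjusted p = 5.09e-05). All 21 protocadherin beta genes were lower (median -1.76, adjusted p = 1.99e-05), and of 13 Cacna calcium channel genes 11 were lower and 1 higher (median -1.66, adjusted p = 0.000869). With an estimated correlation these families had adjusted p = 0.428, 0.438, 0.428, 0.428 and 0.295, whereas the 10 Xlr genes, all higher (median 7.93, adjusted p = 5.45e-21), kept adjusted p = 0.000426.

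Between D6 and D8, 9278 genes changed in TKO and 10571 in WT. In TKO, 12 of 15 core (median 2.44), 15 of 18 naive (1.71) and 14 of 17 formative and primed genes (2.21) rose. There 24 of 30 neural progenitor (-0.91) and 21 of 30 neuron genes (-0.45) fell. In WT, 28 of 30 neuron genes rose (2.29). Of its core genes 6 rose and 6 fell (0.84), of naive 8 and 1 (0.73) and of formative 11 and 4 (0.85). Whether genotypes differed was not tested.

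A few transcripts had very high counts in TKO at D8. ENSMUST00000153941 of Slc38a6 stood at 220 ± 6.87 CPM in WT D8, 711 ± 24 in TKO D0, 12600 ± 268 in TKO D6 and 14900 ± 178 in TKO D8, and ENSMUST00000144826 of Noct at 232 ± 1.46 in WT D8 and 12500 ± 30.3 in TKO D8. Induction of the whole host gene is argued against at Rab3gap1, where the transcript without the shared sequence had a log2 ratio of 0.23 (31.7 ± 0.82 and 37.1 ± 0.184 CPM) and the one with it 6.88. A candidate explanation is 1 repeated sequence carried by many transcripts, since 17 transcripts that share at least 50 31-mers with the Slc38a6 transcript, in 16 genes other than the 5 with such a transcript of 1000 CPM or more, had a median log2 ratio of 5.38, 16 of them higher, while 30 transcripts of 10 of these genes that share none had a median of -0.06 (quartiles -0.62 and 0.59). Which copies of the sequence were transcribed stays open, because kallisto divides such reads between all transcripts that hold it, so the 17 are not independent of each other.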
